A study of Homo sapiens with 8 samples.

How the data were processed

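PC3 is an established human prostate cancer cell line. Per the labels' protocols the cells were grown under 3D conditions in plates of 24 wells, in 1 mL of medium with 3% serum. One arm was transfected for 72 h with small interfering RNA (siRNA) against SF3B2 or with a control siRNA, and the other was given pladienolide B at 0.5 µM for 24 h or dimethyl sulfoxide (DMSO), whose time is not given in the sources used here. SF3B2 is a subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein (snRNP) that recognises the branch point of introns. Pladienolide B is a bacterial macrolide that binds SF3b at SF3B1 and PHF5A and blocks splicing. The design has 4 groups of 2 libraries, 8 libraries in all, each made from total RNA with a stranded kit that selects polyadenylated RNA, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

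The authors deposited 1 table of the whole series with a read count per gene and library, whole numbers that were not normalized. The same deposited table holds TPM, a length-scaled share of transcripts, per library, used here only to check the column totals. A further set of columns holds log2 values that the authors scaled with 1 constant per library, recovered here from the values as log2 of the scaled CPM (counts brought to a common library size) plus 1, and the method behind the constants is not given in the sources used here. The authors' own comparisons stand in the deposited table as a score, a signed fold change in which a lower level is written as minus the inverse ratio. Beside it the authors give a raw and a Benjamini-Hochberg adjusted p-value, per the file headers, from a test that is not stated. Per the submitters' processing notes the tools included Trimmomatic 0.38, HISAT2 2.10, Bowtie2 2.3.5.1 and edgeR, and the genome build was GRCh38, with no roles given. The counting program, its annotation release and whether counting used the strand are not given in the sources used here, so levels of overlapping and antisense genes are uncertain.

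The table lists 17010 genes, and each has at least 1 read in every library. Genes at 0 in any library are therefore absent, and a gene silenced or switched on completely could not be seen. Gene identifiers were matched to 2 annotations of the same build for position, class and exon number. Of the 17010 genes 16758 matched a RefSeq identifier and 15655 a GENCODE gene (release 44). Coordinates are those of GRCh38, counted from 1. Total counts per library ran from 35461248 to 72983584, and the median count per gene was 227 and 223.5 in the pladienolide B libraries against 871 to 1399.5 in the other 6. Intervals given for ratios of reads cover counting error only, at a confidence level of 95%.

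Replicates were compared before they were averaged. The chi-square per degree of freedom over genes was 57.7 for control siRNA, 150 for SF3B2 siRNA, 77.2 for DMSO and 324 for pladienolide B. No pair was within sampling noise, and each library counted as 1 replicate. The median absolute log2 ratio between replicates was 0.17, 0.32, 0.19 and 0.61 in the same order.

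Counts were tested in R 4.3.3 with edgeR 4.0.16, using its quasi-likelihood F-test with robust dispersion, TMM scaling and the filter filterByExpr at a minimum count of 10. This left 16488 genes. All 4 groups entered 1 fit without covariates, which gives 4 residual degrees of freedom, and every test was two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM on the TMM scale. The contrasts were SF3B2 siRNA against control siRNA, pladienolide B against DMSO, the difference of these 2 effects, and control siRNA against DMSO as background. With 2 libraries per group an exact permutation test of single values cannot reach 0.05 and none was run. The 2 main contrasts share no control library, whereas the siRNA contrast and the background contrast share the control siRNA libraries.

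A total of 24 gene lists with 643 entries, some of them older names of the same gene, were fixed from general knowledge. They cover U2 snRNP and SF3b, other spliceosome proteins, SR proteins and hnRNPs, mitosis, DNA replication, homologous recombination, p53 targets, ATF4 targets, endoplasmic reticulum chaperones, heat shock, apoptosis, hypoxia and glycolysis, cholesterol synthesis, interferon response, NF-kB and cytokines, and immediate early genes. The others are single-exon genes, adhesion genes, androgen receptor targets, markers of other cell types, ribosomal proteins, small nucleolar RNA (snoRNA) host genes, histones, and autophagy and lysosome. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log-CPM with a prior count of 2, adjusted over the 24 lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way. All single-exon protein-coding genes of the annotation (268) were tested against the 12652 multi-exon ones in the same way, with p adjusted over the 4 contrasts. Transcript usage was not tested, since the table holds genes and not transcripts.

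The rule for named genes took 7 SF3b subunits, then the 4 largest positive and 4 largest negative changes among called genes. These had to have a mean of at least 5 CPM, groups that did not overlap and an ordinary symbol (no LOC, LINC, MIR, SNOR or antisense name). From each list the rule took the genes with the smallest p, up to 4 where the list was called and 1 otherwise. For the difference of the effects it took 5 genes on each side, and non-overlap was read as every siRNA ratio lying on one side of every drug ratio. Genes named outside the rule are said to be chosen after their values were seen.

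The scripts were tested on simulated counts with 200 changed genes. For the siRNA comparison 0 of 200 genes changed 2-fold were recovered, 177 of those changed 4-fold and 198 of those changed 8-fold, with 1, 13 and 10 false calls. For the drug comparison the numbers were 0, 163 and 196, with 1, 10 and 11 false calls. A simulated shifted list was called and 0 of the other lists were. The simulated genes varied independently, whereas the estimated correlation was 0.65 in the interferon list and 0.97 in the ribosomal protein list. This run therefore cannot show how often camera calls lists whose genes vary together. In the drug comparison itself some genes that changed less than 2-fold were called.

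The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 on the same filtered genes, RLE scaling, library-size scaling alone, no filter on low counts, the replicate number as a block, fits of only the 2 groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. A library left alone in its group was assumed to vary like the other groups. Alternatives added after the data were seen were fits without the pladienolide B libraries, with and without the block, the authors' scaling constants, scaling without ribosomal RNA and mitochondrial genes, and single-exon genes without histones and overlapping genes. Of the patterns weighed at the end, the comparison of single-exon with multi-exon genes was planned, and those of snoRNA and miRNA genes and of the interferon list were noticed in the data first. The bounds for their tests were written before those tests were run, except that for snoRNA and miRNA genes outside other genes. That bound was written afterwards.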

Results

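Gene expression was measured by RNA-seq in PC3 prostate cancer cells grown in 3D culture, in 4 groups of 2 libraries. The study compared loss of the splicing factor SF3B2 with pladienolide B, a small molecule that acts on the same SF3b complex. The SF3B2 siRNA libraries held 61863787 and 48246180 counts and the control siRNA libraries 51661299 and 57417980. The pladienolide B libraries held 41504101 and 35461248 counts and the DMSO libraries 53156845 and 72983584. The groups are marked siSF3B2, sictrl, PlaB and DMSO in the figures. Errors of levels are SDs of 2 libraries and errors of log2 fold changes are standard errors (SE).

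With SF3B2 siRNA the level of its target was several-fold lower and the other SF3b subunits lay near their control levels. SF3B2 lay at 33.2 ± 4.47 CPM with its siRNA and at 228 ± 0.319 CPM with the control siRNA (SD, n = 2), a 6.85-fold lower level. Interferon-response genes formed the group with the largest shift, with all 29 tested members lower than in the control siRNA libraries. By edgeR 0 of these 29 genes passed on its own, and by DESeq2 4 did. The list was called by camera but not with an estimated correlation (adjusted p = 0.684 with an estimated correlation) or by fry (adjusted p = 0.686). The last 2 tests used all 8 libraries and were not rerun without the pladienolide B libraries. The list's mean log2 CPM varied most between the pladienolide B replicates (SD 1.54, against 0.29 to 0.42 in the other groups). Among the 29 genes were RSAD2, an antiviral enzyme, at 18.5 ± 7.52 against 85.7 ± 31.7 CPM, and IFIT1, which binds viral RNA, at 84.2 ± 29.1 against 283 ± 87.7 CPM. Ribosomal protein genes lay slightly higher, by a median log2 fold change of 0.42 over 48 genes, with 0 of 48 passing edgeR, adjusted p = 0.684 with an estimated correlation, and no call without SF3B2 siRNA replicate 1 (0.15, adjusted p = 0.129, over the alternatives 6.78e-18 to 0.129).

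SF3B2 spans 66052364 to 66069308 on the plus strand of chromosome 11 (GRCh38), and its log2 fold change was −2.78 ± 0.24 (SE). By edgeR its adjusted p = 0.0513 was the smallest of the comparison, so 0 of 16488 genes passed the threshold, with 638 at an unadjusted p under 0.05 (274 higher and 364 lower). DESeq2 called 34 genes, 8 higher and 26 lower, with adjusted p = 1.97e-25 for SF3B2. Without pladienolide B replicate 1 or 2 the edgeR test called SF3B2 alone (adjusted p = 0.00663 and adjusted p = 0.00629), and over the alternatives its adjusted p ran from 1.97e-25 to 1.00. In the authors' deposited table an adjusted p under 0.05 was reached by 14 genes, 4 higher and 10 lower, and all 14 were among the 34 of DESeq2. The subunits SF3B1, SF3B3, SF3B4, SF3B5, SF3B6 and PHF5A had log2 fold changes between −0.19 and 0.22, each with adjusted p = 1.00.

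Several genes called by DESeq2 and not by edgeR were chosen after their values were seen. PRSS35, a serine protease-like protein, had a log2 fold change of −2.51 ± 0.29 and TAF13, a subunit of the general transcription factor TFIID, one of −1.74 ± 0.23. TRIM22 and TRIM5, both antiviral restriction factors, had values of −2.42 ± 0.54 and −1.11 ± 0.19. Their adjusted p by DESeq2 was 2.26e-10, 7.40e-09, 0.00215 and 9.53e-05 in this order, and 2.26e-10 to 1.00, 7.40e-09 to 1.00, 0.000263 to 1.00 and 9.53e-05 to 1.00 over the alternatives. TRIM22 and TRIM5 overlap neighbouring genes on the same strand, so their counts are uncertain, as are those of IFIT2, ASNS and SNHG16 below.

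By camera 9 of the 24 lists were called with SF3B2 siRNA, 3 higher and 6 lower, at a preset correlation between genes. With an estimated correlation 0 of the 24 lists were called, each of these 9 having adjusted p = 0.684 with an estimated correlation, and by fry 0 were called (smallest adjusted p = 0.686). The interferon list had a median log2 fold change of −1.25 (adjusted p = 6.03e-17, and adjusted p = 0.684 with an estimated correlation), led by RSAD2 (−2.22), IFIT1 (−1.75), IFIT2 (−1.60) and IFIT3 (−1.57). With edgeR 0 of its 29 members passed over all genes and 5 passed when adjusted over the list alone, all of them lower. DESeq2 called 4 members, RSAD2, IFIT1, IFIT2 and IFIT3 (adjusted p by DESeq2 of 9.53e-05, 0.00100, 0.0137 and 0.0248). The same 4 genes had an adjusted p under 0.05 in the authors' deposited table. The other lower lists were histones (median −0.35, adjusted p = 0.000217), ATF4 targets of amino acid supply such as ASNS and SLC7A11 (−0.35, adjusted p = 0.000217), cholesterol synthesis (−0.22, adjusted p = 0.000311), endoplasmic reticulum chaperones with HYOU1 (−0.38, adjusted p = 0.000339), and NF-kB targets with the chemokine genes CXCL1 and CXCL2 (−0.37, adjusted p = 0.00272). Of the 22 NF-kB targets 16 lay lower and 6 higher, among the latter the chemokine gene CCL2. The higher lists were ribosomal proteins (adjusted p = 2.47e-07), mitotic genes such as CCNB1 and KIF4A (median 0.32, adjusted p = 0.000431), and snoRNA host genes such as SNHG16 (0.17, adjusted p = 0.0401). The 8 lists other than the interferon list also had adjusted p = 0.684 with an estimated correlation. The remaining 15 lists had medians between −0.17 and 0.26 and were not called by camera, with adjusted p from 0.0645 to 0.912. They were the 3 splicing lists, DNA replication, homologous recombination, p53 targets, heat shock, apoptosis, hypoxia and glycolysis, immediate early genes, single-exon genes, adhesion genes, androgen receptor targets, markers of other cell types, and autophagy. In these 15 lists 0 genes passed edgeR over all genes, and SF3B2 itself, in the U2 snRNP list, was the 1 member that passed when adjusted over the list alone.

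Of the 9 called lists the interferon list was called without each of the 8 libraries in turn. Without SF3B2 siRNA replicate 1 the calls of ribosomal proteins (adjusted p = 0.129) and NF-kB targets (adjusted p = 0.113) were lost, and without SF3B2 siRNA replicate 2 those of histones (adjusted p = 0.126) and mitotic genes (adjusted p = 0.476). ATF4 targets, cholesterol synthesis and endoplasmic reticulum chaperones lost theirs without SF3B2 siRNA replicate 2 (adjusted p of 0.699, 0.476 and 0.878) or control siRNA replicate 1 (0.0618, 0.0957 and 0.388). The snoRNA host genes lost theirs without SF3B2 siRNA replicate 1 (0.782), control siRNA replicate 2 (0.188), or DMSO replicate 1 or 2 (0.0576 and 0.0571). The first value given for each list is the highest over its alternatives, the estimated correlation and fry apart, and the lowest values were 6.78e-18, 0.00187, 5.66e-06, 6.76e-07, 3.31e-09, 1.19e-07, 6.85e-09 and 0.00597 in the order of naming.

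The sizes of 6 of these shifts changed when single libraries were left out, given here relative to all genes. For ATF4 targets the value of −0.36 became −0.87 without SF3B2 siRNA replicate 1, −0.07 without replicate 2, −0.12 without control siRNA replicate 1 and −0.54 without replicate 2. For endoplasmic reticulum chaperones −0.40 became −0.86, −0.07, −0.06 and −0.65 in the same order. The mean log2 CPM of the chaperones was 7.97 and 7.20 in SF3B2 siRNA replicates 1 and 2, and 8.28 and 7.71 with control siRNA. With DMSO it was 8.16 and 7.31, so replicate 1 was the higher in each of these groups. Leaving out 1 library thus also changes the balance of replicate numbers, and whether these pair libraries is not known. Cholesterol synthesis went from −0.23 to −0.43 and −0.03 without SF3B2 siRNA replicate 1 and 2 and to −0.13 without control siRNA replicate 1. Without SF3B2 siRNA replicate 1 and 2, ribosomal proteins went from 0.40 to 0.15 and 0.65, mitotic genes from 0.30 to 0.48 and 0.15, and snoRNA host genes from 0.16 to 0.06 and 0.31.

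Another 4 lists were called only when a library or whole groups were left out or with the replicate block. Hypoxia and autophagy genes were called without SF3B2 siRNA replicate 1 (adjusted p of 0.00175 and 0.0101), control siRNA replicate 2 (0.000606 and 0.0441) or pladienolide B replicate 1 (0.0463 and 0.0364) or 2 (0.0461 and 0.0371). Heat shock genes were called without SF3B2 siRNA replicate 1 (0.000871) or control siRNA replicate 2 (0.0151), and adhesion genes without pladienolide B replicate 1 (0.0239) or 2 (0.0244). The highest adjusted p over the alternatives was 0.987, 0.699, 0.958 and 0.532 in this order.

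The control siRNA and DMSO libraries served as the background of both treatments. Between them 0 genes were called by edgeR, with 152 at an unadjusted p under 0.05, and 0 by DESeq2, with 158. Mitotic genes lay lower with control siRNA than with DMSO, by a median log2 fold change of −0.50 over 34 genes. Interferon genes lay lower too, by −0.45 over 29 genes with all 29 negative. The other lists called by camera were DNA replication (−0.23), snoRNA host genes (−0.21), heat shock (−0.23) and homologous recombination (−0.16), all lower, and cholesterol synthesis (0.14), endoplasmic reticulum chaperones (0.20), adhesion genes (0.21) and ATF4 targets (0.14), all higher. In all camera called 10 of 24 lists here, 4 higher and 6 lower with control siRNA, 0 were called with an estimated correlation (smallest adjusted p = 0.725 with an estimated correlation) and 0 by fry (smallest adjusted p = 0.977). Of the 6 lists called in both this contrast and the SF3B2 siRNA contrast, 5 went in opposite directions and 1, the interferon list, in the same direction. The 2 contrasts share the control siRNA libraries, whose chance values enter them with opposite signs.

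**Figure D1:**
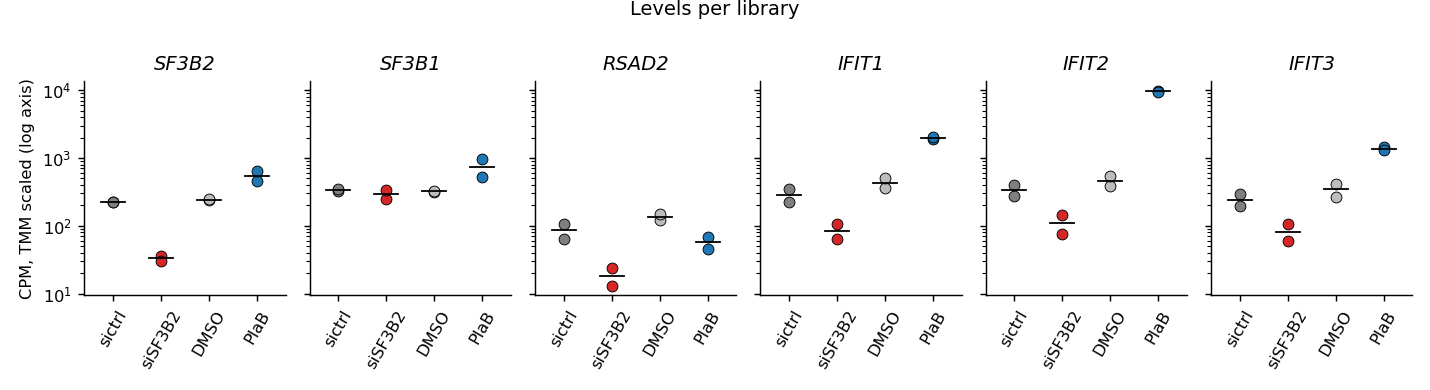
Level of SF3B2, SF3B1, RSAD2, IFIT1, IFIT2 and IFIT3 in CPM on a log axis, by treatment group. Points are the 2 libraries of each group and lines their mean, and SF3B2 lay at a mean of 33.2 CPM with SF3B2 siRNA against 228 CPM with control siRNA.

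Pladienolide B changed most of the measured transcriptome. Of 16488 genes tested 11212 were called, 5358 higher and 5854 lower, and 10042 of them had an absolute log2 fold change of at least 1. Among genes of the splicing machinery 22 of 30 SR proteins and hnRNPs, 22 of 29 other spliceosome proteins and 18 of 21 U2 snRNP proteins rose, with 0, 1 and 2 falling, while 22 of 30 genes of glycolysis and the hypoxia response fell and 1 rose. These lists were called by camera and by fry (adjusted p = 0.00037, 7.66e-05, 0.00037 and 0.0043 by fry). They were not called with an estimated correlation (adjusted p = 0.441, 0.204, 0.441 and 0.839 with an estimated correlation). NDRG1, a hypoxia-induced stress gene, fell from 4037 ± 470 CPM to 78.0 ± 64.0 CPM (SD, n = 2), and SRSF2, a splicing factor of the SR family, rose from 206 ± 3.08 to 3322 ± 587 CPM. The immediate early transcription factor gene JUN rose from 174 ± 26.2 to 2231 ± 970 CPM.

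Among called genes with an ordinary symbol and a mean of at least 5 CPM, small RNAs left aside, the largest increases were those of the pseudogene PRXL2AP2, the opioid receptor gene OPRD1, the neuronal transcription factor gene TBR1 and the ephrin gene EFNA2. OPRD1, on chromosome 1 from 28812170 to 28871267, rose by a log2 fold change of 9.22 ± 0.53 (adjusted p = 1.75e-05), from 0.489 ± 0.227 to 286 ± 9.75 CPM. TBR1 and EFNA2 rose by 8.16 ± 0.40 and 8.15 ± 0.45. PRXL2AP2 had a fitted value of 9.86 ± 0.89, but only 2 and 1 reads in the DMSO libraries against 807 and 254 with the drug, a ratio of 1065 with a counting interval of 364 to 5175. As a pseudogene it can share reads with its parent gene. Under the same limits the largest decreases were those of the thyroid hormone receptor gene THRB (−6.89 ± 0.49), the autophagy regulator gene DEPP1 (−6.72 ± 0.86), TRIM22 (−6.60 ± 0.70) and PRRG1 (−6.53 ± 0.47), which encodes a membrane protein with a Gla domain. PRRG1 had 9 and 2 reads with the drug against 1242 and 1823 with DMSO, a ratio of 0.0108 (counting interval 0.00539 to 0.0194). TBR1, THRB, TRIM22 and PRRG1 overlap another gene on the same strand and DEPP1 one on the opposite strand, so their counts are uncertain.

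The SF3b subunits rose by log2 fold changes of 1.17 ± 0.23 for SF3B2, 1.20 ± 0.31 for SF3B1, 1.82 ± 0.19 for SF3B3, 3.21 ± 0.25 for SF3B4, 3.10 ± 0.45 for SF3B5, 1.48 ± 0.21 for SF3B6 and 2.14 ± 0.23 for PHF5A. SF3B2 reached 545 ± 123 CPM with the drug against 243 ± 8.04 with DMSO. With library-size scaling alone the calls of SF3B2 (0.30, adjusted p = 0.279) and SF3B1 (0.34, adjusted p = 0.381) were lost, and over the alternatives their adjusted p ran from 2.22e-07 to 0.279 and from 0.000104 to 0.381. SF3B1 also lost its call without DMSO replicate 1 (adjusted p = 0.0553) or DMSO replicate 2 (adjusted p = 0.0536), and its value was 0.70 without pladienolide B replicate 2.

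Direction in this comparison depends on how libraries are scaled. The median log2 fold change of all genes was −0.11 with TMM, 0.05 with RLE scaling, −0.17 with the authors' constants and −0.97 with library-size scaling alone. Calls split into 5358 higher and 5854 lower with TMM and into 3313 higher and 8446 lower with library-size scaling alone. DESeq2 called 5935 genes higher and 5614 lower, and the authors' deposited table lists 5323 higher and 6125 lower at an adjusted p under 0.05. Of the 11212 calls 97.2% were kept in direction by DESeq2, 96.1% with RLE scaling and 81.8% with library-size scaling alone, where 366 called genes changed sign without being called in the other direction. Genes of nuclear ribosomal RNA took 5.48% and 5.40% of counts in the pladienolide B libraries and 1.68% to 3.50% in the other 6.

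By camera 8 lists were called with pladienolide B, and their changes are given relative to the median of all genes. SR proteins and hnRNPs, which bind pre-mRNA and guide splice site choice, had 22 of 30 members higher and 0 lower, with a median 2.06 above that of all genes (adjusted p = 7.18e-05, and adjusted p = 0.441 with an estimated correlation). They were led by SRSF4 (3.61 ± 0.22), SRSF2 (4.01 ± 0.26) and HNRNPF (3.33 ± 0.23). Of the other spliceosome proteins 22 of 29 rose and 1 fell (1.89 above all genes, adjusted p = 7.98e-05, and adjusted p = 0.204 with an estimated correlation), with PRPF3 of the U4/U6 snRNP at 3.03 ± 0.20 and the Sm protein gene SNRPD1 at 3.42 ± 0.24. In the U2 snRNP list 18 of 21 rose and 2 fell (1.82 above all genes, adjusted p = 0.000214, and adjusted p = 0.441 with an estimated correlation), among them the SF3a subunits SF3A2 (3.26 ± 0.26) and SF3A1 (2.41 ± 0.21). Immediate early genes had 22 of 31 higher and 2 lower (1.98 above all genes, adjusted p = 9.26e-05, and adjusted p = 0.492 with an estimated correlation), with the transcription factor genes ATF3 (3.79 ± 0.22), JUN (3.68 ± 0.35) and KLF4 (2.11 ± 0.19). Of the single-exon genes on the fixed list 19 of 29 rose and 2 fell (1.78 above all genes, adjusted p = 0.000363, and adjusted p = 0.441 with an estimated correlation), with PURB, a DNA-binding protein, at 4.07 ± 0.27 and TAF7, a TFIID subunit, at 4.47 ± 0.25. Some single-exon genes, JUN among them, are also immediate early genes. TAF7 overlaps another gene on the same strand, and SRSF2 lies in an intron of a gene on the opposite strand. With library-size scaling alone the medians of these 5 lists stayed positive, from 0.80 for single-exon genes to 1.09 for SR proteins and hnRNPs.

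Ribosomal protein genes had 32 of 48 members higher and 0 lower (1.38 above all genes, adjusted p = 0.000184, and adjusted p = 0.918 with an estimated correlation), with RPL19 at 1.68 ± 0.32 and RPL37 at 1.42 ± 0.29. Without pladienolide B replicate 1 the list lay only 0.62 above all genes, and its mean log2 CPM was 10.53 and 9.27 in the pladienolide B libraries against 8.97 and 8.59 with DMSO. These genes share sequence with many pseudogenes, so their counts are uncertain, and fry did not call the list (adjusted p = 0.103). With library-size scaling alone the median was 0.39 and RPL37, RPL6 and RPL18 lost their calls, with adjusted p over the alternatives from 1.63e-06 to 0.109, from 2.32e-06 to 0.0687 and from 5.35e-06 to 0.0931. Among the lists that fell, hypoxia and glycolysis had 22 of 30 lower and 1 higher (−1.81 relative to all genes, adjusted p = 0.000568, and adjusted p = 0.839 with an estimated correlation). Its members included NDRG1 (−5.69 ± 0.68), which overlaps another gene on the same strand, the mitophagy receptor gene BNIP3 (−3.56 ± 0.29) and the aldolase gene ALDOC (−1.95 ± 0.19). Cholesterol synthesis had 17 of 24 lower and 5 higher (−1.39, adjusted p = 0.0211, and adjusted p = 0.839 with an estimated correlation), with the sterol enzyme genes SC5D (−2.76 ± 0.20) and MVK (−3.31 ± 0.29). For these 8 lists the counts adjusted over the list alone were the same as over all genes. With an estimated correlation 0 of 24 lists were called, and by fry 13 were, 7 higher and 6 lower. Among the 13 were all of these 8 lists except ribosomal proteins.

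The interferon list, which was not called (adjusted p = 0.667), split. IFNB1, which encodes interferon beta, rose by 5.59 ± 0.42, and 8 members in all rose while 9 fell (8 and 8 adjusted over the list alone). The listed genes IFIT2 (4.38) and IFIT1 (2.20) rose and MX2 (−5.21) fell, chosen after their values were seen. The list's mean log2 CPM was 4.70 and 6.88 in the 2 pladienolide B libraries against 6.84 and 7.25 with DMSO. Without pladienolide B replicate 2 the list was called lower (adjusted p = 0.0441), and over the alternatives its adjusted p ran from 0.0441 to 0.978.

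In the other 15 lists that were not called by camera (adjusted p from 0.0621 to 0.921), many single genes changed. Of all genes tested 68.0% were called, which is the share to set beside the counts below. By fry androgen receptor targets (adjusted p = 0.0043), adhesion (0.021), homologous recombination (0.028) and apoptosis genes (0.028) were called lower. NF-kB targets (0.039) and snoRNA host genes (0.041) were called higher by fry. Adhesion genes had 3 higher and 18 lower of 34 (17 lower adjusted over the list alone), with the transcription factor gene SNAI1 at 3.36 ± 0.28. ATF4 targets had 6 higher and 14 lower of 26, and androgen receptor targets 1 higher and 5 lower of 8, with the protease gene TMPRSS2 at −2.90 ± 0.26. NF-kB targets had 10 higher and 3 lower of 22, with the cytokine gene IL1B at −3.85 ± 0.29. Heat shock genes had 12 higher and 4 lower of 21, with the co-chaperone gene STIP1 at 2.03 ± 0.21. Histones had 9 higher and 2 lower of 14, with H2BC4, which overlaps another gene on the same strand, at −3.46 ± 0.20. The snoRNA host genes had 6 higher and 1 lower of 15, with SNHG17 at 5.21 ± 0.33. Homologous recombination genes had 3 higher and 12 lower of 27 (11 lower adjusted over the list alone), with the end-resection factor gene RBBP8 at −2.86 ± 0.22. DNA replication had 7 higher and 10 lower of 34, with the clamp loader gene RFC4 at −3.32 ± 0.24. Mitotic genes had 7 higher and 11 lower of 34 (6 and 10 adjusted over the list alone), with the cyclin gene CCNB1 at 2.31 ± 0.22. The apoptosis list had 9 higher and 10 lower of 27 (10 and 10 adjusted over the list alone).

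The p53 target list had 3 higher and 6 lower of 19, with the phosphatase gene PPM1D at 2.97 ± 0.27. Autophagy had 7 higher and 8 lower of 22, with GABARAPL1 at −3.55 ± 0.29, and endoplasmic reticulum chaperones 1 higher and 5 lower of 21, with ATF6 at −1.35 ± 0.23. Markers of other cell types had 2 higher and 3 lower of 11, with the monocyte receptor gene CD14 at 5.85 ± 0.38. The median of the NF-kB list changed from 0.67 to −0.19 and that of the snoRNA host genes from 0.38 to −0.49 with library-size scaling alone. The medians of autophagy (−0.05) and endoplasmic reticulum chaperones (−0.03) became 0.10 and 0.12 with RLE scaling. Heat shock and snoRNA host genes were called higher without pladienolide B replicate 2 (adjusted p = 0.0441 and adjusted p = 0.0387, with ranges over the alternatives up to 0.247 and 0.554). Adhesion genes were called lower without pladienolide B replicate 2 or DMSO replicate 1 (adjusted p = 0.00509 and adjusted p = 0.0492), and with no filter on low counts (adjusted p = 0.0438), with a range over the alternatives up to 0.149.

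**Figure D2:**
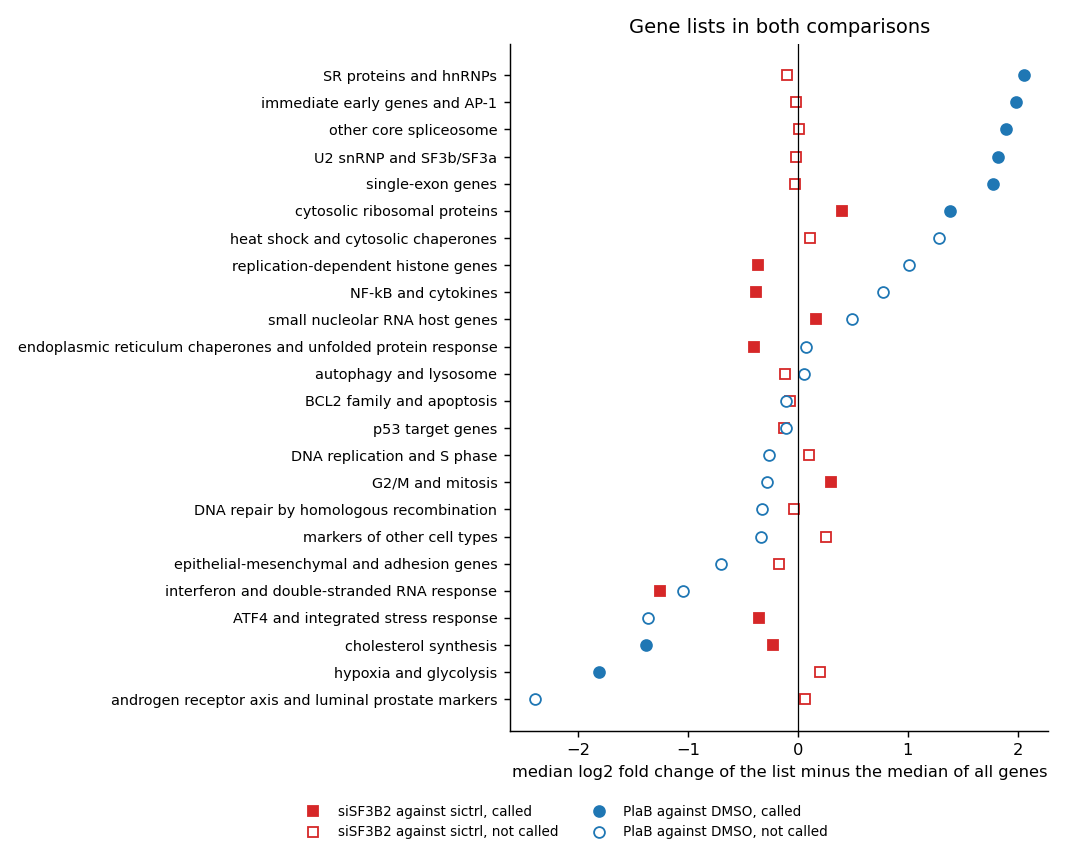
Median log2 fold change of each of the 24 gene lists minus the median of all genes, for SF3B2 siRNA against control siRNA and pladienolide B against DMSO. Filled points are lists called by camera, and the interferon list lay at −1.26 with SF3B2 siRNA while SR proteins and hnRNPs lay at 2.06 with pladienolide B.

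The 2 treatments were then compared gene by gene. All 7 SF3b subunits responded differently, each being higher with the drug relative to its control than with the siRNA, from −1.37 for SF3B6 to −3.94 ± 0.33 for SF3B2 (siRNA effect minus drug effect). The difference itself was called for 8861 genes, 4702 where the siRNA effect was the higher and 4159 where it was the lower. Among called genes with an ordinary symbol and a mean of at least 5 CPM, small RNAs left aside, the largest positive differences were those of THRB (6.86 ± 0.59), the prostaglandin-degrading enzyme gene HPGD (6.70 ± 1.10, and 10.15 without pladienolide B replicate 2), PRRG1 (6.40 ± 0.58), the actin-associated protein gene LIMCH1 (6.34 ± 0.72) and the steroid dehydrogenase gene HSD17B2 (6.31 ± 0.45). Under the same limits the largest negative ones were those of PRXL2AP2 (−9.90 ± 1.46), OPRD1 (−9.39 ± 0.69), the growth factor gene FGF18 (−8.11 ± 0.35), the read-through gene NDUFC2-KCTD14 (−7.38 ± 0.93) and the complement factor gene CFP (−7.21 ± 0.62).

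With library-size scaling alone the split of the differences became 7323 and 2463. NDUFC2-KCTD14 and CFP overlap other genes on the same strand. The difference for SF3B1 (−1.40, adjusted p = 0.0281) was not called with library-size scaling alone (adjusted p = 0.374) or without SF3B2 siRNA replicate 1 (0.103), control siRNA replicate 1 (0.0710) or 2 (0.0819), or DMSO replicate 1 (0.0837) or 2 (0.0818), and over the alternatives its adjusted p ran from 0.00164 to 0.374, with a value of −0.90 without pladienolide B replicate 2. Across 16488 genes, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.12 and rho = 0.10, with r = 0.05 without SF3B2 siRNA replicate 1, 0.06 without control siRNA replicate 2 and 0.18 without control siRNA replicate 1. By edgeR 0 genes were called in both comparisons, where 0 siRNA calls allow no overlap by chance, and 638 genes had an unadjusted p under 0.05 with the siRNA. By DESeq2 19 genes were called in the same direction, 4 higher and 15 lower where independent lists give 2.88 and 8.85. Another 9 were called in opposite directions, for which no such value was computed. With the drug DESeq2 called 5935 genes higher and 5614 lower of 16488, so a large overlap can arise by chance. Of the 24 lists camera called 7 for the difference, 1 higher and 6 lower, with 0 called with an estimated correlation (smallest adjusted p = 0.203 with an estimated correlation) and 8 by fry. The 6 lower ones were the 3 splicing lists, immediate early genes, single-exon genes and ribosomal proteins, and the higher one was hypoxia and glycolysis.

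Genes without introns need no splicing and were set against all others. With pladienolide B 174 of 268 single-exon protein-coding genes rose and 14 fell, against 3646 risen and 5191 fallen of 12652 multi-exon genes. The medians were 1.61 and −0.39, a difference of 2.0 (adjusted p = 9.23e-15 by camera, and adjusted p = 0.0241 with an estimated correlation). The same difference was 0.05 with SF3B2 siRNA (adjusted p = 0.612; −0.03 without SF3B2 siRNA replicate 1) and −0.02 between the control libraries (adjusted p = 0.612). The difference between the treatments was −1.99 (adjusted p = 1.03e-14, and adjusted p = 0.0241 with an estimated correlation).

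**Figure D3:**
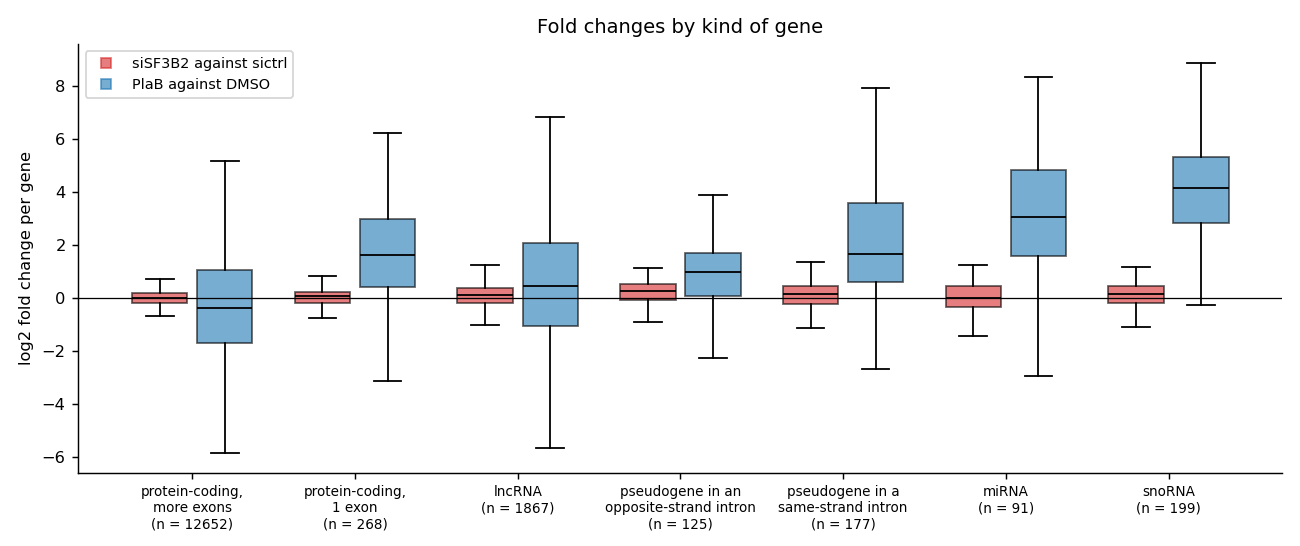
Log2 fold change of genes by class for SF3B2 siRNA against control siRNA and pladienolide B against DMSO. Boxes span the quartiles with the median as a line and points beyond the whiskers are not drawn, and with pladienolide B the median was 1.61 for single-exon and −0.39 for multi-exon protein-coding genes.

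Genes of snoRNAs and microRNAs (miRNAs) were examined after their values were seen. With pladienolide B 183 of 199 snoRNA genes and 68 of 91 miRNA genes rose, with 0 and 2 falling, and medians of 4.13 and 3.03. Genes of snoRNAs took 0.212% and 0.176% of counts in the pladienolide B libraries and 0.00901% to 0.0118% in the other libraries. Such genes could pass the filter through the pladienolide B libraries alone, and low counts elsewhere leave little room for a fall. The same low counts limit what the siRNA comparison can detect. Of the 199 snoRNA and 91 miRNA genes 153 and 61 lie in an intron of a gene on the same strand. SNORD33 and SNORD34, which lie in introns of the ribosomal protein gene RPL13A, rose by 9.36 ± 0.51 and 9.29 ± 0.46, and RPL13A, which overlaps another gene on the same strand, by 1.66 ± 0.44. Of 153 snoRNAs inside 87 host genes 149 had a higher log2 fold change than their host, with medians of 4.40 and 1.21, as had 55 of 58 miRNAs inside 54 hosts (3.24 and 0.96). With SF3B2 siRNA 0 of the 290 snoRNA and miRNA genes were called by edgeR, with 3 snoRNA and 2 miRNA genes at an unadjusted p under 0.05, and their median was 0.10 (adjusted p = 0.0463 by camera, and adjusted p = 0.301 with an estimated correlation). The call of RPL13A was lost with library-size scaling alone (adjusted p = 0.125) and without DMSO replicate 2 (adjusted p = 0.0742), and over the alternatives its adjusted p ran from 5.87e-05 to 0.125, with a value of 0.89 without pladienolide B replicate 1. These short RNAs are poorly captured by a library of polyadenylated RNA, so their counts need not follow the mature RNAs.

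**Figure D4:**
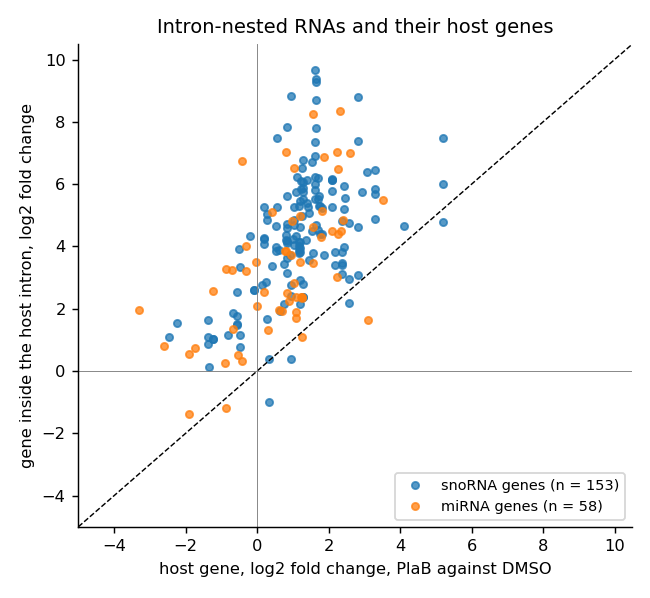
Log2 fold change with pladienolide B against DMSO of 153 snoRNA and 58 miRNA genes inside introns, against that of their host genes. Each point is a gene and the dashed line marks equal change, and 149 of the snoRNAs lay above it.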

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

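The check of the class median under library-size scaling and the test of snoRNA and miRNA genes outside other genes were chosen only after the result was seen, and the snoRNA and miRNA genes were chosen after their values were seen.

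The difference between the siRNA effect and the drug effect singled out 3 results. That of SF3B2 was in part set by the design, since SF3B2 is the siRNA's own target. The treatments also differed in transfection and in time, 72 h for the siRNA and 24 h for the drug. SF3B2 differed by −3.94 on the log2 scale, being lower with its siRNA and higher with the drug, with an adjusted p below the threshold in each of the 15 alternatives (3.78e-30 to 0.00194). The median difference of the 290 snoRNA and miRNA genes was −3.76 (adjusted p = 4.95e-30, and adjusted p = 0.00385 with an estimated correlation), with 224 of them called. Single-exon genes differed from multi-exon genes by −1.99 (adjusted p = 1.03e-14, and adjusted p = 0.0241 with an estimated correlation). These last 2 differences mostly repeat the drug effects, which were 3.86 and 2.0, as the siRNA values were 0.10 and 0.05.

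The rise of snoRNA and miRNA genes with pladienolide B was weighed against 3 technical explanations. For a less complete selection of polyadenylated RNA, the comparison set was 36 genes of unpolyadenylated RNAs, taken to have promoters of their own. Their median of 1.43 lay −2.43 from the 3.86 of the 290 snoRNA and miRNA genes (permutation p = 1e-05, the smallest the permutations can give). However, 21 of the 36 were tRNA genes (0.53) that matched no GENCODE gene. Nuclear and mitochondrial tRNA genes were not told apart, so promoters of their own were not established for them. The snRNA genes (2.1, 11 of 12 called higher) and rRNA genes (2.59, 12 of 12) rose. This comparison therefore cannot decide how much of the rise came from the selection. Against scaling between libraries, 90.04% of the called genes (226 of 251) stayed called higher with library-size scaling alone, which passed the bound of 90% by less than its counting spread, while the class median stayed at 3.00. Reads of retained host introns counted to the nested genes remain a candidate explanation for those genes. Pseudogenes in same-strand introns had a median of 1.64 and those in opposite-strand introns one of 0.99, a difference of 0.65 (permutation p = 0.00014, 177 and 125 genes). The snoRNA and miRNA genes in same-strand introns lay higher, at 4.40 and 3.02. The pseudogenes therefore cannot show that intron reads account for their whole rise. The 20 snoRNA and miRNA genes counted as not nested in another gene had a median of 1.96. It lay 1.16 above the 0.79 of 452 pseudogenes that are not nested (permutation p = 0.0396). Of these small RNA genes 12 of 13 snoRNA genes (median 2.63) and 4 of 7 miRNA genes (1.52) were called higher and 1 miRNA gene lower. Nesting was judged from the canonical transcript of each host gene, so introns of other transcripts could still contain these genes. The comparison therefore cannot exclude reads of retained introns for them. A change in the small RNAs themselves through the blocked splicing was not tested and stays open.

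The rise of single-exon genes relative to multi-exon genes with pladienolide B was weighed against GC content, transcript length and expression level. With these 3 as terms in a linear model over 12920 genes the single-exon coefficient went from 1.95 to 1.66 (95% interval 1.42 to 1.89), so 84.9% of it was kept. Without histones and genes inside or overlapping another gene, 167 single-exon genes gave a difference of 1.90. The length of the gene along the genome was not a term, and no single-exon gene was longer than 9540 bases. Over all protein-coding genes the drug effect was lower in longer genes (Spearman rho = −0.32). Genes with 2 exons also rose, with a median of 1.18. The model therefore cannot separate the lack of introns from short gene length. The pattern may reflect that transcripts without introns escape a block of splicing, a hypothesis that the planned comparison does not test by itself, and a lower total of spliced RNA per cell was not measured and stays open.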

How the results depend on the processing

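The fits of 3 groups, the authors' scaling constants, the omission of ribosomal RNA and mitochondrial genes, and RLE scaling for the lists with the drug were chosen only after the data were seen. The number of genes called with SF3B2 siRNA was 0 by edgeR, 34 by DESeq2, 1 with RLE scaling, 1 with only the 2 groups compared, 1 with 3 groups, 1030 with 3 groups and the replicate block (25 of the 29 interferon genes lower among them), and 0 to 1 without each library. For SF3B2 with its siRNA the value was −2.79 by DESeq2 and with RLE scaling, −2.78 with 2 groups, with 3 groups and with 3 groups and the block, and −2.93 to −2.65 without each library. Fewer groups leave out the pladienolide B libraries, whose replicates had the widest spread, and the cause of the other changes was not tested. The correlation of the effects was 0.0498 to 0.184 without each library, and the overlap was 19 by DESeq2. The lists called with SF3B2 siRNA numbered 4 to 12 without each library (4 without SF3B2 siRNA replicate 2), 0 with an estimated correlation and 0 by fry, and with pladienolide B 0 with an estimated correlation and 13 by fry. The single-exon difference with SF3B2 siRNA was −0.0321 to 0.0895 without each library. The counts for the drug (9031 to 12351 without each library) and for the difference (6680 to 11075) stayed within 1.5 times.

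Of the other values, single genes with the drug gave 1061 with the same call and 11 with a lost one (7 genes), with the siRNA 1069 with the same, 41 gained (33 genes) and 6 moved, and in the difference 174 with the same and 6 lost, all of SF3B1. Lists gave 387 with the same call, 32 lost, 24 gained and 13 moved with the siRNA, and 375, 9, 12 and 12 with the drug, estimated correlations and fry included. The replicate numbers share only a number, and the labels pair no libraries. With the block in all 4 groups 0 genes were called with the siRNA (983 at an unadjusted p under 0.05), 5545 higher and 6191 lower with the drug, and 5205 and 4482 in the difference. Replicate differences correlated at 0.54 between the siRNA groups, 0.63 and 0.51 of control and SF3B2 siRNA with DMSO, and 0.18, 0.25 and 0.14 of control siRNA, SF3B2 siRNA and DMSO with the drug, too few pairs to settle a pairing. Transcript usage and alternatives for TPM were not run. The pladienolide B libraries had median counts per gene of 227 and 223.5, which limits genes of low level there.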

Other observations

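The bins of exon number and gene length and the list of genes with the widest replicate ratio were chosen only after the data were seen.

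Over 12920 protein-coding genes the log2 fold change with pladienolide B was lower in longer genes (Spearman rho = −0.32) and in genes with more exons (rho = −0.27). The medians were 1.61 for genes with 1 exon, 1.18 for those with 2, 0.39 for 3 to 5, −0.29 for 6 to 10, −0.74 for 11 to 20 and −1.03 for over 20. By quartile of gene length they were 0.56, −0.13, −0.61 and −1.11. With SF3B2 siRNA the values of rho were −0.15 and −0.13.

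The 2 pladienolide B libraries stood further apart than those of any other group. Of the 50 genes with the widest log2 ratio of replicate 1 against replicate 2, 39 were lower and 11 higher in replicate 1, the widest being TGIF2-RAB5IF (−8.02) and, among the higher ones, ZNF761 (5.93). Members of the interferon list made up 6 of the 50, all lower, among them IFI27 (−6.44), IFI6 (−5.51) and MX1 (−4.94), and 25 of its 29 tested genes were lower. The mean log2 CPM of the interferon list was 4.70 and 6.88 in these libraries, 5.0 and 5.59 with SF3B2 siRNA, 6.23 and 6.78 with control siRNA, and 6.84 and 7.25 with DMSO.

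The lower interferon list with SF3B2 siRNA was weighed against 2 technical explanations. A raised interferon level in the control siRNA libraries would need a positive value against DMSO, and the list's median there was −0.45. A single deciding library would end the call, and without each of the 4 siRNA libraries in turn the median stayed between −1.58 and −0.95 (adjusted p up to 1.47e-08 at the preset correlation, while with all libraries it was adjusted p = 0.684 with an estimated correlation). Since DMSO and control siRNA differ by transfection, and a difference between the cultures of each group was not tested, a loss of interferon signalling after SF3B2 depletion may be 1 explanation among others.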
